A study of Synechocystis sp. PCC 6803 with 3 samples.

How the data were processed

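Total RNA of 2 mutant strains of the cyanobacterium Synechocystis was compared on 3 two-colour Agilent arrays. Both strains lack photosystem I. One of them, called the Scp-less strain here, also lacks the family of small chlorophyll-binding proteins, and the other, called the PSI-less strain, served as its comparison. Per the labels, each array carried the PSI-less RNA in the Cy5 channel and the Scp-less RNA in the Cy3 channel, and the arrays were biological replicates 1, 2 and 3. All arrays had the same dye orientation, so a dye effect particular to a gene cannot be separated from a strain effect. The labels do not say how the replicate cultures were separated, so p-values rest on the spread between these arrays. The labels' labelling protocol describes a single-dye procedure with 7 µg of RNA, although the labels give 2 dyes per array. The direction of the ratios was therefore also checked against the scp genes.

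The scanner files hold spot intensity values, and per the file headers these are the median pixel brightness of each spot and of its local background in each channel. The submitters' processing notes name Agilent Feature Extraction 10.5.1.1. The deposited files also carry processed intensity values and a log10 ratio of Cy5 over Cy3 from the scanner software. That ratio lay within 0.01 of the log10 ratio of the processed signals for 98.5% to 98.9% of spots per array. The authors also deposited a table with 1 value per gene and array. The values the authors deposited in it were taken as log2 ratios, because the value of scpD was about the same size as its log2 ratio from the scanner files, and how they were made is not given in the sources used here. The log base, normalization and centring of the table thus stay unknown. Its column medians were 0.002, 0.011 and -0.002, and its sign was taken from scpB to scpE, so that these are low in it by that choice.

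Each array held 15208 gene spots of 8091 probes for 3264 genes and 536 control spots. Of the genes, 61 had 1 probe, 1611 had 2, 1560 had 3 and 32 had 4. Gene spots were well above background in 99% to 100% of cases in Cy3 and in 100% in Cy5. Median spot signals were 1125.5, 2016.5 and 3694.25 in Cy3 on arrays 1, 2 and 3, and 1675.75, 6010 and 4719.25 in Cy5, over median backgrounds of 45 to 48 and 56 to 67. No gene spot was marked as saturated, and 1, 10 and 4 gene spots were marked as outliers and left out. The standard deviation of a single spot, estimated from the differences between duplicate spots of a probe, was 0.073, 0.102 and 0.059 on the log2 scale. The number of arrays limits the precision.

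Background was corrected by normexp with an offset of 50, followed by loess within each array with control spots at weight 0, in limma 3.58.1 under R 4.3.3. The plan had named the mean pixel signal as foreground. The files carry the median, which was used instead. Ratios were turned so that a positive log2 ratio means a higher level in the Scp-less strain. Spots of a probe were averaged, and then the probes of a gene. Probes had to be well above background in at least 1 channel on at least 2 arrays, judged by at least 0.5 of their spots, and 1 probe was left out by this rule. Each gene was tested with limma's lmFit and eBayes on its 3 ratios against 0, with Benjamini-Hochberg adjustment over 3264 genes and a threshold of 0.05. Spreads are standard deviations over the 3 arrays. The p-values rest on another spread, since eBayes draws the variance of each gene toward that of all genes. For phoA (sll0654) the SD was 2.97 and the standard error tested was 1.04. For scpE (ssr1789) they were 0.006 and 0.065. Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over 25 lists. Camera with an estimated correlation and fry were alternatives. Camera compares the genes of a list with the other genes. Fry does not, and tests whether the genes of a list move on balance in one direction. With an estimated correlation, camera called 0 of 25 lists in either source. Its smallest adjusted p was 0.583 in the scanner files and 0.699 in the authors' table. A call lost under that setting therefore does not set 1 list apart from another. The estimated correlations did differ among the lists called in the scanner files. They were 0.99 for phosphate uptake, 0.63 for ATP synthase, 0.56 for hydrogenase and 0.42 for ribosomal proteins. For the other called lists they were 0.01 to 0.16. Where genes of a list move together more than the preset assumes, the camera adjusted p at the preset can be too small. Correlations between arrays are across genes, which are not independent replicates.

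The 26 gene lists, with 398 genes, were written before the data were examined, as were the tests, most of the other settings and the rule for named genes. One list, the pair of photosystem I core genes, was too short for a list test. Planned lists of transposase genes and plasmid genes could not be formed, since the files give no product text and the highest locus number was 3829. The files give locus tags without gene names. None of them (0) matched the reference table of 3347 genes, so that table was not used. Gene names and functions are those written with the lists from general knowledge of this organism, printed beside the locus tag of the file. Genes outside the lists are unnamed here. No genome was used, so no coordinates are given.

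The rule for named genes took, in each direction, the 15 genes with the largest mean log2 ratio among those past the threshold with the same sign on all 3 arrays and well above background in at least 1 channel on all 3. It added the scp and psa genes and up to 4 members per list with the largest absolute log2 ratio, those past the threshold first. Of the 15 genes per direction, 7 were in a list among the higher and 7 among the lower. For the authors' table the same rule was applied afterwards.

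Alternatives were no background correction, another offset, the scanner software's log ratio, median centring, scale or Aquantile normalization between arrays, the median or the brightest probe of a gene, single probes, other filters, outlier spots kept, eBayes with a trend or robust priors, the authors' table, and each array left out. The tests were checked on simulated data for this comparison, with 200 of 3264 genes changed. Of the changed genes, 61.2% were recovered at a log2 ratio of 0.5, 86.6% at 1 and 98.5% at 2, with 13 false calls and 0 calls of the wrong sign. In a simulation with 1 list moved by 0.5, that list was called and 0 others were. Genes were drawn independently of each other there. The simulation therefore cannot show how often camera calls a list wrongly when its genes move together. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.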

Results

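Transcript levels were measured in 2 strains of Synechocystis, a unicellular cyanobacterium that can grow on glucose. The PSI-less strain is labelled as lacking photosystem I. The Scp-less strain is labelled as lacking, in addition, the small Cab-like proteins ScpA to ScpE, which bind chlorophyll and resemble a single helix of plant light-harvesting proteins. Cultures were grown at 30 °C in dim light of 4 to 5 µmol photons per square metre and second with 10 mM glucose. The series' title frames the comparison as one of carbon and nitrogen balance. There were 3 arrays, each with both strains on it, and every ratio is the Scp-less over the PSI-less strain.

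The scp genes were examined first. Transcripts of scpD (ssr2595) were 41.2-fold lower in the Scp-less strain, with a log2 ratio of -5.36 ± 0.35 (SD, n = 3; limma adjusted p = 0.000223). The log2 ratio of scpC (ssl2542) was -3.10 ± 0.39, that of scpE (ssr1789) was -1.45 ± 0.01 and that of scpB (ssl1633) was -1.20 ± 0.24, each past the threshold (limma adjusted p = 0.000615, 0.000543 and 0.00193). The 2 probes of scpE moved in opposite directions over the arrays, with SDs of 0.11 and 0.10, so the SD of their average was smaller. The probes of scpC disagreed. Probes 51 and 149 gave -5.05 and -5.02, while probe 2 gave 0.78, and with the brightest probe alone the gene's value turned to 0.78. ScpA is a domain of ferrochelatase, the enzyme that makes haem, and its gene hemH (slr0839) gave -0.17 ± 0.24, which did not pass (limma adjusted p = 0.234). In the Scp-less strain the mean log2 levels were 9.26 for scpD, 11.43 for scpC, 10.98 for scpE and 11.27 for scpB. All probes of these genes were well above background in Cy3 on all 3 arrays, so signal remained in the strain labelled as lacking them. A probe outside a deleted part does not check the deletion, and the deleted parts are not given in the sources used here. As a list, the 5 genes were lower (median -1.45, camera adjusted p = 0.00163), with 4 past the threshold, also when adjusted over the list alone. With an estimated correlation the adjusted p = 0.583, and with the brightest probes the adjusted p = 0.0896. The strain is labelled as lacking the products of these genes, so a lower list checks the labels and is not evidence of regulation.

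Both strains are labelled as lacking photosystem I, but which parts of its core genes, psaA and psaB, were removed is not given in the sources used here. Both genes gave signals well above background in both channels. The mean log2 level of psaB was 15.71 in the PSI-less and 13.35 in the Scp-less strain, and that of psaA was 12.26 and 13.06. The log2 ratio of psaB (slr1835) was -2.36 ± 0.21 and that of psaA (slr1834) was 0.80 ± 0.09 (limma adjusted p = 0.000543 and 0.00197). The 4 probes of psaB gave -2.50 to -2.29. Of the psaA probes, probe 2006 was well above background in the Cy3 channel on 1 array only.

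**Figure D1:**
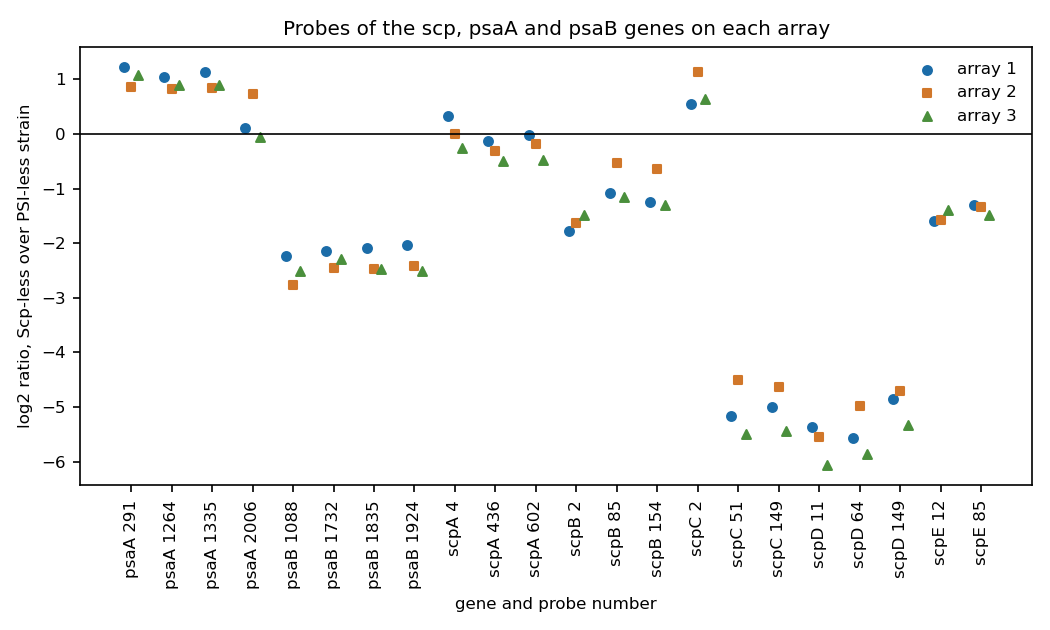
Log2 ratio of the Scp-less over the PSI-less strain (vertical axis) for each probe of the scp, psaA and psaB genes (horizontal axis), with 1 point per array. Probes of scpD lie between -6.07 and -4.71, whereas probe 2 of scpC lies above 0 on all 3 arrays.

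Across the genome, 757 genes were higher and 725 were lower in the Scp-less strain, or 45.4% of 3264 genes. Most differences were small, and 46 genes were higher and 41 lower by at least 2-fold. Beside the scp genes, the transcript most reduced was lilA (slr1544), which encodes another small light-harvesting-like protein, at -4.35 ± 0.64 (20.4-fold lower, limma adjusted p = 0.000914). No coordinates were used, so whether a deletion also affected genes beside it was not examined, for lilA or any other gene. The unnamed genes sll0253 and slr1634 followed psaB and the chaperone gene clpB1, with levels 3.99-fold and 3.69-fold lower. Among the higher genes with the same response on all 3 arrays were the unnamed ssr2016 at 2.82 ± 0.30 and slr0376 at 2.58 ± 0.23. They were joined by chlN (slr0750), a subunit of the light-independent protochlorophyllide reductase, at 1.82 ± 0.14, and by the major pilin gene pilA1 (sll1694) at 1.68 ± 0.12. Counts depended on the arrays: 396 genes were higher and 378 lower without array 1, and 447 and 395 without array 2. With arrays 1 and 2 averaged as 1 replicate, a setting chosen after the data were seen, 452 were higher and 409 lower. Array 3 was the most distinct, with correlations across genes of 0.73 and 0.71 to arrays 1 and 2, against 0.89 between those.

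The list for inorganic carbon uptake was lower in the Scp-less strain. Of 17 genes, 10 fell, 1 rose and 6 did not pass, with the same counts when adjusted over the list alone, and the list's median was -0.40 (camera adjusted p = 0.00232). The call was lost with an estimated correlation (adjusted p = 0.583), as was that of every list called at the preset correlation. The genes ndhF4 (sll0026) and ndhD4 (sll0027), of the constitutive carbon dioxide uptake complex, fell by 0.82 and 0.79 on the log2 scale with SDs of 0.10 and 0.06. The bicarbonate transporter genes bicA (sll0834) and sbtA (slr1512) gave -0.69 ± 0.23 and -0.66 ± 0.18. With the brightest probe, ndhF4 lost its call at -0.27. In the authors' table the list leaned the other way, with 8 genes higher and 3 lower by the test and camera's direction up, and was not called by camera (median -0.02, mean 0.31, adjusted p = 0.284; fry adjusted p = 0.0193). There sbtA had 0.70.

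For the other carbon lists no call was made. Among 22 carboxysome and Calvin cycle genes, 4 rose and 9 fell (median -0.09, camera adjusted p = 0.334). Adjusted over the list alone, 5 rose and 9 fell. Phosphoglycerate kinase, pgk (slr0394), and ribose phosphate isomerase, rpiA (slr0194), were lower at -0.81 ± 0.22 and -0.66 ± 0.21, while the carboxysome shell gene ccmO (slr0436) was higher at 0.57 ± 0.04. Median centring in place of loess brought this list past the threshold (median -0.29, adjusted p = 0.0112). With the brightest probe, ccmO lost its call at 0.24. Of 22 genes of glycogen and sugar catabolism, 2 rose and 6 fell (median -0.14, camera adjusted p = 0.263), or 2 and 4 when adjusted over the list alone. Those lower included glgC (slr1176), for ADP-glucose pyrophosphorylase, at -0.79 ± 0.18 and glgA1 (sll0945), for glycogen synthase, at -0.47 ± 0.05, although glgA1 lost its call at -0.10 with the scanner software's log ratio. Of 16 genes of the tricarboxylic acid cycle and pyruvate metabolism, 4 rose and 4 fell (median -0.08, camera adjusted p = 0.487), or 4 and 5 when adjusted over the list alone, though fry called the list (adjusted p = 0.034). The succinate dehydrogenase subunit gene sdhB2 (sll0823) gave -0.82 ± 0.11 and the fumarase gene fumC (slr0018) gave -0.44 ± 0.07, and fumC lost its call with the brightest probe at -0.23. The list's other succinate dehydrogenase genes, chosen after their values were seen, went the other way. They were sdhA (slr1233) at 0.23 ± 0.08 and sdhB1 (sll1625) at 0.24 ± 0.11 (limma adjusted p = 0.0446 and 0.0484). Among those that rose were the succinyl-CoA synthetase gene sucD (sll1557) at 0.83 ± 0.55 and the pyruvate dehydrogenase gene pdhB (sll1721) at 0.32 ± 0.03. Both lost their call without array 1 (0.73 and 0.33) and without array 2 (0.63 and 0.32), and pdhB also with the scanner software's log ratio (0.19).

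Nitrogen genes moved in both directions. Of 30 genes for nitrogen uptake and assimilation, 5 rose, 11 fell and 14 did not pass, also when adjusted over the list alone, and the list was not called (median -0.18, camera adjusted p = 0.0905). The gene pirA (ssr0692), for a regulator of arginine synthesis that binds the PII protein, rose by 1.31 ± 0.11 on the log2 scale (limma adjusted p = 0.00125). The gene gifA (ssl1911), for an inactivating factor of glutamine synthetase, rose by 0.98 ± 0.14, and nblA1 (ssl0452), needed for phycobilisome breakdown, by 1.00 ± 0.34. The urea transporter gene urtA (slr0447) gave -0.91 ± 0.66 and lost its call without array 1 (-0.76, adjusted p = 0.118) and without array 2 (-0.69, adjusted p = 0.0946). The list passed the threshold without array 1 (median -0.26, adjusted p = 0.0288) and with median centring (median -0.24, adjusted p = 0.0333). Of 11 genes for arginine and cyanophycin, the storage polymer of aspartate and arginine, 1 rose and 4 fell, also when adjusted over the list alone. Their median was 0.03 while the mean was -0.07 and camera's direction was down, and the list was not called (camera adjusted p = 0.558). The arginine synthesis genes argC (sll0080) and argB (slr1898) gave -0.47 ± 0.17 and -0.39 ± 0.02, and argB lost its call without array 1 (-0.38, adjusted p = 0.0509), with the brightest probe (-0.09) and with the scanner software's log ratio (adjusted p = 0.0531). The gene that rose, argJ (sll1883), gave 0.40 ± 0.15 and lost its call without array 1 (0.37) and without array 2 (0.34).

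**Figure D2:**
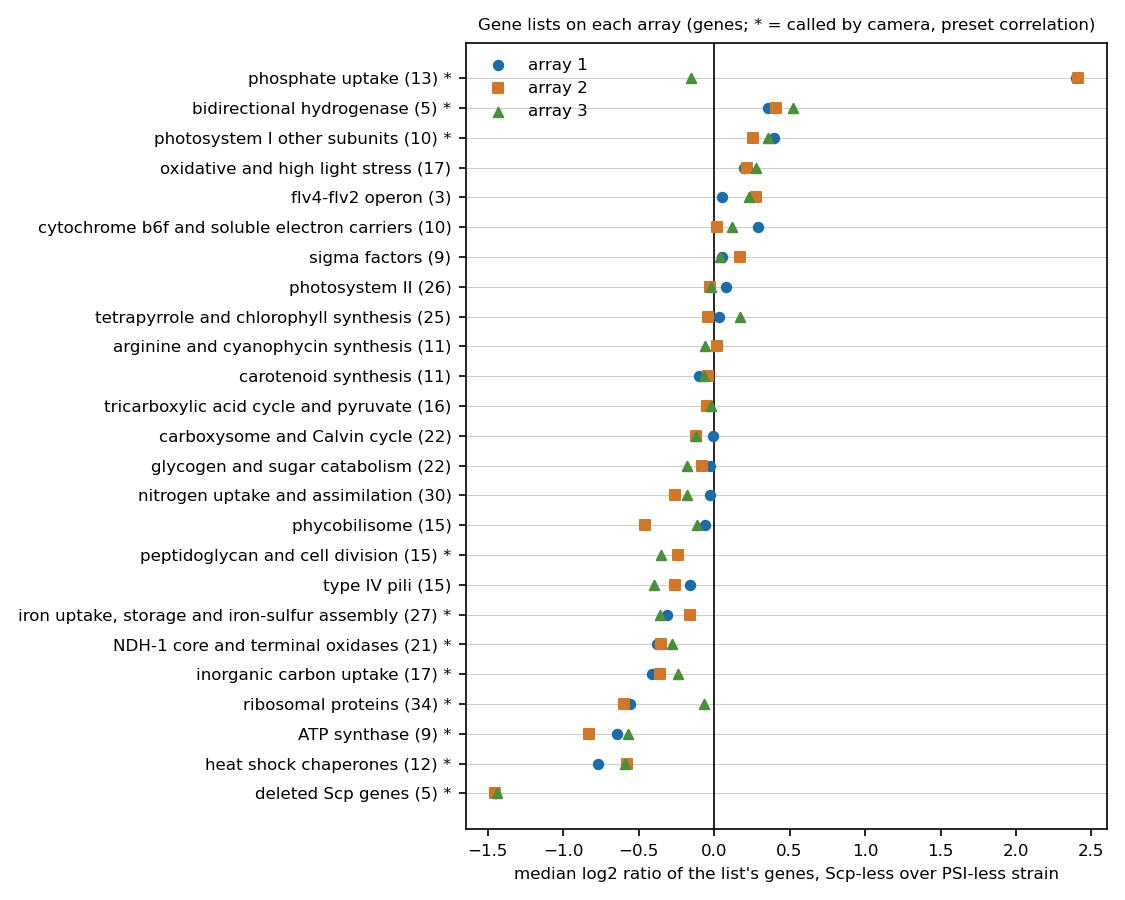
Median log2 ratio of each gene list (horizontal axis) on each of the 3 arrays, with the number of genes in brackets and an asterisk for lists called by camera at the preset correlation. The deleted Scp genes lie lowest, and phosphate uptake lies at 2.40 and 2.41 on arrays 1 and 2 and at -0.15 on array 3.

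Among photosynthesis genes, the list of other photosystem I subunits was higher. Of 10 such genes, 6 rose and 0 fell (median 0.48, camera adjusted p = 0.0177), and 8 rose when adjusted over the list alone. The adjusted p = 0.583 with an estimated correlation, and 0.16 with median centring. The gene psaM (smr0005) rose by 0.91 ± 0.38 and psaD (slr0737) by 0.57 ± 0.21 on the log2 scale, the latter without a call at 0.06 under median centring. Photosystem II genes went both ways, with 6 rising and 6 falling of 26, also when adjusted over the list alone. Their median was 0.06, their mean was -0.04, camera's direction was down and the list was not called (adjusted p = 0.817). The D1 protein genes psbA2 (slr1311) and psbA3 (sll1867) gave -0.97 ± 0.17 and -0.98 ± 0.21. These genes are near-identical, so their values are uncertain as to which of the pair they measure. The small subunit gene psbL (smr0007) rose by 0.62 ± 0.32 and lost its call under median centring (0.29). Of 15 phycobilisome genes, 5 fell and 0 rose (median -0.24, camera adjusted p = 0.0723), or 4 when adjusted over the list alone, among them the linker gene apcE (slr0335) at -0.63 ± 0.32. That list passed the threshold with median centring (median -0.59, adjusted p = 0.00202) without array 1 (median -0.31, adjusted p = 0.0208) and with arrays 1 and 2 averaged (adjusted p = 0.0482). Without array 1, apcE lost its call (-0.65, adjusted p = 0.0576).

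Tetrapyrrole and chlorophyll synthesis genes were not called as a list (median 0.03, camera adjusted p = 0.604), with 7 of 25 rising and 5 falling, also when adjusted over the list alone. Beside chlN, its partner chlL (slr0749) rose by 1.43 ± 0.35 on the log2 scale (limma adjusted p = 0.00221). The magnesium chelatase subunit gene chlD (slr1777) rose by 0.57 ± 0.09. Of 11 carotenoid genes, 2 rose and 3 fell (median -0.08, camera adjusted p = 0.513), or 2 and 4 when adjusted over the list alone. The gene dxs (sll1945) gave 0.49 ± 0.14 and lost its call with the scanner software's log ratio (0.43, adjusted p = 0.0535). The gene dxr (sll0019) gave -0.37 ± 0.11 and lost its call without array 2 (-0.32, adjusted p = 0.0761). In the operon of the flavodiiron proteins Flv4 and Flv2, flv4 (sll0217) rose by 0.47 ± 0.10 and the other members did not pass (median 0.19, camera adjusted p = 0.237), also when adjusted over the list alone. Of 10 genes of the cytochrome b6f complex and soluble carriers, 3 rose, or 1 when adjusted over the list alone (median 0.17, camera adjusted p = 0.263), and the median was -0.11 with median centring. The one with the smallest spread, petC3 (sll1182), gave 0.65 ± 0.10.

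The lists for respiration and ATP synthase were lower, though some members rose. Of 21 genes of the NDH-1 core and the terminal oxidases, 11 fell and 3 rose, or 13 and 3 when adjusted over the list alone (median -0.31, camera adjusted p = 0.0177). The adjusted p = 0.583 with an estimated correlation, 0.126 with the brightest probes and 0.103 with the scanner software's log ratio. The genes ndhB (sll0223) and ndhF1 (slr0844) gave -0.62 ± 0.13 and -0.60 ± 0.06, whereas ndhH (slr0261) rose by 0.58 ± 0.06. The other members that rose, chosen after their values were seen, were ndhN (sll1262) at 0.48 ± 0.27 and cydA (slr1379), of the quinol oxidase, at 0.55 ± 0.37. Its partner cydB (slr1380) gave 0.32 and did not pass, while ctaD1 (slr1137), of cytochrome c oxidase, gave -0.53 ± 0.06. Of 9 ATP synthase genes, 7 fell and 0 rose, also when adjusted over the list alone (median -0.68, camera adjusted p = 0.00163). The adjusted p = 0.583 with an estimated correlation. Values were -0.86 ± 0.18 for atpF (sll1324) and -0.83 ± 0.20 for atpG (sll1323). The 5 genes of the bidirectional hydrogenase rose, also when adjusted over the list alone (median 0.49, camera adjusted p = 0.0174), with hoxU (sll1223) at 0.54 ± 0.17 and hoxE (sll1220) at 0.49 ± 0.08. That call was lost with an estimated correlation (adjusted p = 0.583) and with the brightest probes (adjusted p = 0.0508).

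The iron and heat shock lists were lower. Of 27 genes of iron uptake, storage and iron-sulfur assembly, 14 fell and 2 rose, also when adjusted over the list alone (median -0.27, camera adjusted p = 0.00371). The adjusted p = 0.583 with an estimated correlation. The iron-binding protein genes futA2 (slr0513) and futA1 (slr1295) gave -1.19 ± 0.25 and -1.14 ± 0.33, and sufD (slr0076), for iron-sulfur cluster assembly, gave -1.14 ± 0.22. Of 12 heat shock chaperone genes, 7 fell and 0 rose, also when adjusted over the list alone (median -0.69, camera adjusted p = 0.00289). The adjusted p = 0.583 with an estimated correlation. The log2 ratios of clpB1 (slr1641), groEL2 (sll0416) and hspA (sll1514) were -2.08 ± 0.59, -1.07 ± 0.13 and -1.03 ± 0.29.

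Of 17 genes of oxidative and high light stress, 9 rose and 3 fell, or 9 and 5 when adjusted over the list alone, without a call by camera (median 0.23, adjusted p = 0.145), though fry called it (adjusted p = 0.034). The peroxiredoxin genes ahpC (sll1621) and prx (slr1198) rose 2.14-fold and 2.13-fold, with SDs of 0.34 and 0.36 on the log2 scale, while lilA, also in this list, fell. Of 15 genes of peptidoglycan synthesis and cell division, 8 fell and 1 rose, also when adjusted over the list alone (median -0.25, camera adjusted p = 0.0177), with murF (slr1351) at -0.89 ± 0.06. The adjusted p = 0.583 with an estimated correlation, and the call was also lost without array 3 (median -0.19, adjusted p = 0.0657), with the median of probes (0.0679) and with the scanner software's log ratio (0.0836). Of 15 type IV pilus genes, 2 rose and 7 fell, also when adjusted over the list alone (median -0.25, camera adjusted p = 0.145). Those that rose were the pilin genes pilA1 and pilA2 (sll1695), the latter at 1.11 ± 0.45, while pilA10 (slr2016) and pilA11 (slr2017) gave -0.94 ± 0.14 and -0.89 ± 0.21. With the scanner software's log ratio, pilA11 lost its call at -0.58 (adjusted p = 0.0588). Of 9 sigma factors, 2 rose and 1 fell, or 3 and 2 when adjusted over the list alone (median 0.14, or 0.01 with median centring and camera's direction turned, camera adjusted p = 0.557), with sigC (sll0184) at 0.82 ± 0.01 and sigE (sll1689) at -0.83 ± 0.15.

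Phosphate genes included the transcript with the highest mean ratio but differed between arrays. Alkaline phosphatase, phoA (sll0654), had log2 ratios of 5.24, 5.27 and 0.11 on arrays 1, 2 and 3, and the nuclease gene nucH (sll0656) had 4.17, 3.90 and 0.05. The phosphate transporter genes pstA2 (slr1249) and pstB2 (slr1250) showed the same split, with 2.40, 2.51 and 0.06 for pstA2. Of 13 genes, 5 rose and 0 fell, or 7 when adjusted over the list alone (median 1.51, camera adjusted p = 0.00754). The adjusted p = 0.611 with an estimated correlation. Without array 3 the list's median was 2.43. Those 4 named genes lost their call without array 1 (phoA 2.69, adjusted p = 0.151), without array 2 (phoA 2.67, adjusted p = 0.124), with arrays 1 and 2 averaged and with robust priors. Ribosomal protein genes had a similar split, with list medians of -0.56, -0.60 and -0.07. Of 34 genes, 16 fell and 2 rose, or 21 and 2 when adjusted over the list alone (median -0.46, camera adjusted p = 0.00163). The adjusted p = 0.611 with an estimated correlation. Among them rpsC (sll1804) and rplN (sll1806) gave -0.72 ± 0.58 and -0.67 ± 0.53, and both lost their call without array 1 (-0.50 and -0.54) and without array 2 (-0.61 and -0.50).

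**Figure D3:**
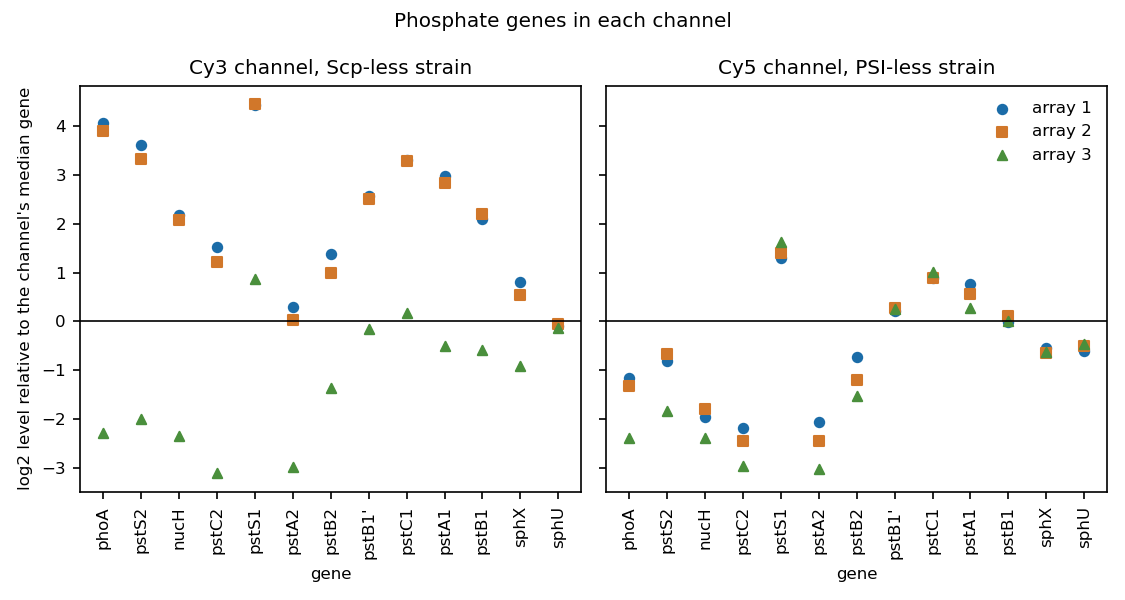
Log2 level of each of the 13 phosphate genes relative to the median gene of the channel (vertical axis), in the Cy3 channel with Scp-less RNA and the Cy5 channel with PSI-less RNA, with 1 point per array. In Cy3 the genes of arrays 1 and 2 lie above those of array 3, with phoA at 4.06, 3.90 and -2.28.

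The authors' deposited table gave another picture of many genes. Across genes, its mean correlated with that of the scanner files at r = 0.20 (Spearman's rho = 0.12), while its own 3 columns correlated at 0.87 to 0.94. Its values could not be rebuilt from the scanner files. By limma, 1127 genes were higher and 1089 lower in the table. Of those, 353 were also higher and 270 also lower in the scanner files, where 261.4 and 241.9 would overlap among independent lists, and 413 had opposite calls against 502.9. The table's sign was taken from scpB to scpE, which had values of -4.93 for scpD, -2.21 for scpC, -1.37 for scpE and -0.94 for scpB, while hemH had 0.04. If the table's values are log2 ratios, 22 genes other than the scp genes were called in both sources with at least a 2-fold difference. Of these, 20 had the same direction, psaB among them, and sufD and pilA2 did not. Other genes named above with the opposite sign in the table were sbtA, argJ, pdhB, dxr, nucH, pstA2, pstB2, pilA1, pilA10, pilA11, nblA1, urtA, flv4, pgk, rpiA, ccmO, sdhB2, apcE, chlD, futA1, futA2, prx, rplN, hoxE, slr1634 and hemH. The lists for inorganic carbon uptake, photosystem I, iron, phosphate, NDH-1 and hydrogenase also turned camera's direction and were not called by camera.

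In the table, nitrogen lists were lower. Of 30 nitrogen genes, 18 were lower and 6 higher by the test, or 20 and 6 when adjusted over the list alone (median -0.51, camera adjusted p = 0.0157; adjusted p = 0.699 with an estimated correlation). All 11 arginine and cyanophycin genes were lower, also when adjusted over the list alone (median -0.66, camera adjusted p = 0.000388; adjusted p = 0.699 with an estimated correlation). Heat shock chaperones (median -0.54, camera adjusted p = 0.0374) and ribosomal proteins (median -0.17, camera adjusted p = 0.015) were lower too. For both of these too the adjusted p = 0.699 with an estimated correlation. The deleted Scp genes were also called (camera adjusted p = 0.0248, or 0.699 with an estimated correlation), but their direction in the table was set by the choice of its sign. The inactivating factor genes gifB (sll1515) and gifA had 3.04 ± 0.36 and 2.78 ± 0.38 and pirA had 2.43 ± 0.13 on the table's scale. The nitrite reductase gene nirA (slr0898) had -2.64 ± 0.34 and the nitrate transporter gene nrtA (sll1450) had -2.07 ± 0.51. In the scanner files gifB, nirA and nrtA gave -0.29, -0.19 and -0.01, the latter pair without a call.

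**Figure D4:**
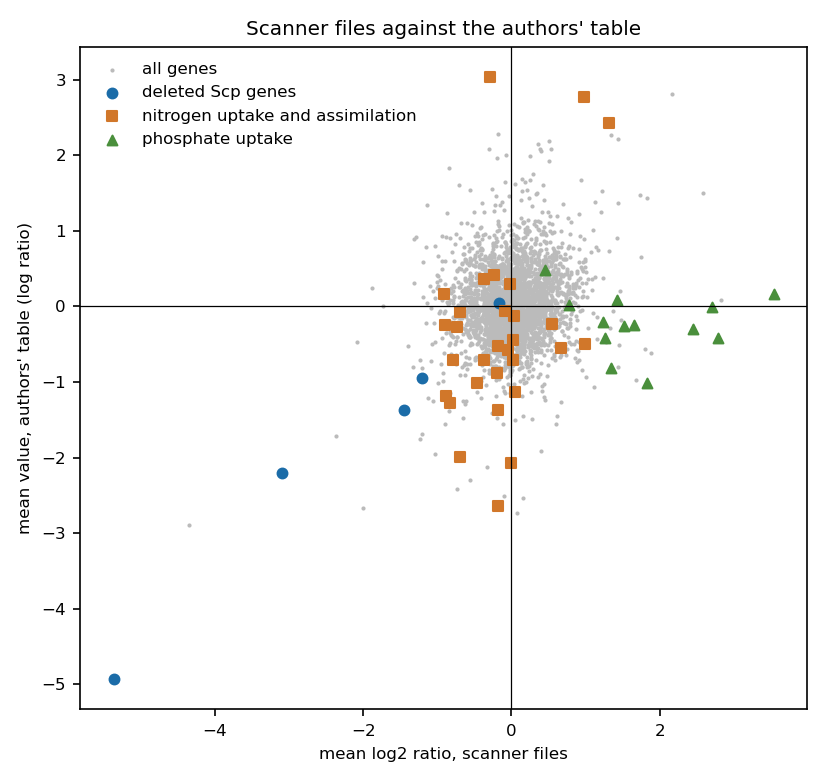
Mean log2 ratio from the scanner files (horizontal axis) against the mean value in the authors' table (vertical axis), with 1 point per gene and lists marked. The correlation across genes is 0.20, and scpD lies at -5.36 and -4.93.

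After the loess step, spike-in controls gave median log2 ratios of 0.08, 0.53 and 0.26 over 10 probes on arrays 1, 2 and 3. That step was fitted to the gene spots, so these ratios are relative to the genes. A ratio of 0 would need the same mix in both channels and balanced amounts of RNA, so they do not measure the dye balance.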

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

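Averaging arrays 1 and 2 as 1 replicate, and every alternative run within the authors' table, were chosen after the data were seen, and the other alternatives were planned. For the changes listed here the cause was not tested. The counts of 757 higher and 725 lower genes stayed within 1.5 times under the other background, normalization, filter, probe-averaging and eBayes settings, but 958 of 1482 calls remained with the scanner software's log ratio and 1163 with the brightest probe. Leaving out 1 array gave 396 to 768 higher and 378 to 716 lower genes, averaging arrays 1 and 2 gave 452 and 409, and single probes gave 1787 and 1773 of more features tested. By the authors' values 1127 were higher and 1089 lower. Of the 1482 calls, 623 were called again in the same direction and 446 were no longer called. The sign changed for 635 of them, whether called again or not. The median-pixel setting equalled the values reported, and leaving out saturated spots was not run, since 0 were saturated. With an estimated correlation, camera called 0 of 25 lists in either source, so a loss there does not set a list apart. Among those lost were the deleted Scp genes (-1.45) and inorganic carbon uptake (-0.40), both at adjusted p = 0.583. Those lost in the table included the deleted Scp genes (-1.37), nitrogen (-0.51) and arginine (-0.66), all at 0.699. Fry gained the tricarboxylic acid cycle (-0.08) and oxidative stress (0.23), both at adjusted p = 0.034. In the authors' table, where 67.9% of genes were called, it called 19 lists against 5 by camera. Camera compares a list with the other genes and fry does not, so these counts answer different questions. Among the 19 were carbon uptake (-0.02), glycogen (-0.39) and the tricarboxylic acid cycle (-0.14), all at 0.0193. In the scanner files fry lost phosphate (0.204) and ribosomal proteins (0.164). Median centring gained nitrogen (-0.24) and the Calvin cycle (-0.29) and turned sigA to -0.02, cytochrome b6f to -0.11 and the direction of the sigma factor list at 0.01. The scanner software's log ratio turned flv2 to -0.03 and camera's direction for the arginine list, whose median was 0.04. The brightest probe turned scpC to 0.78, hemH (scpA) to 0.03, cpcG2 to 0.16, ndhD2 to 0.06, sigB to 0.32 and the tetrapyrrole list to -0.03, and ended the call of the deleted Scp genes (-1.06, adjusted p = 0.0896). Over the arrays left out, list medians ran from -0.26 to -0.14 for nitrogen, from 0 to 0.06 for photosystem II, from -0.06 to 0.07 for tetrapyrroles, and in the table from -0.09 to 0.19 for iron, from 0.02 to 0.34 for hydrogenase and from -0.03 to 0.06 for sigma factors. Of the named genes, 28 lost their call without array 1, 20 without array 2 and 4 without array 3. The authors' table brought the nitrogen list (-0.51, adjusted p = 0.0157) and the arginine list (-0.66, adjusted p = 0.000388) past the threshold. It turned camera's direction, though not always the sign of the median, for these lists, given with their medians in the table: carbon uptake -0.02, the flv4 operon 0.05, the Calvin cycle 0.04, photosystem II 0.18, photosystem I -0.15, iron 0.05, phosphate -0.24, NDH-1 0.32, pili 0.60, hydrogenase 0.13 and sigma factors 0. It turned these genes to negative values: nucH -0.01, slr0581 -0.62, slr1608 -0.56, pilA1 -0.97, pstA2 -0.24, pstB2 -0.26, sll0549 -0.18, nblA1 -0.49, argJ -0.75, flv4 -0.26, cp12 -0.06, ccmO -0.30, pdhB -0.17, psaL -1.56, chlD -0.26, crtP -0.22, prx -0.08, petJ -1.91, pilA2 -1.07 and hoxE -0.78. It turned these to 0 or above: slr1634 0.25, sll1009 0, slr1552 0.30, sll0263 0.89, sll1688 0.92, hemH 0.04, urtA 0.17, sbtA 0.70, pgk 0.72, rpiA 0.14, sdhB2 0.08, psbQ 0.26, apcE 0.25, apcC 0.28, dxr 0.10, futA2 0.13, futA1 0.05, sufD 1.34, rplN 0.07, rplE 0.05, pilA10 0.60, pilA11 0.93 and murA 0.26. Signals stood well above background in at least 99% of gene spots in each channel, and 1 probe was left out as dim.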

Other observations

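The tests below were chosen after the results were seen, except the one on shuffled gene names, and the genes in this paragraph were also chosen after their values were seen. The nitrogen list as a whole was not called in the scanner files, and these are single members of it. The nitrate reductase gene narB (sll1454) gave a log2 ratio of -0.90 ± 0.39 (SD, n = 3; limma adjusted p = 0.00751), the ammonium transporter gene amt1 (sll0108) gave -0.89 ± 0.37 (limma adjusted p = 0.0067) and the urea transporter gene urtB (slr1200) gave -0.70 ± 0.22 (limma adjusted p = 0.00486), each with the same sign on all 3 arrays. In the authors' table these genes also had negative values, of -0.25, -1.18 and -1.99. Other members for the same substrates were lower or did not pass in the scanner files. The nitrate transporter genes nrtB (sll1451), nrtC (sll1452) and nrtD (sll1453) passed at -0.47, -0.79 and -0.74, as did urtA, while amt2 (sll1017) and amt3 (sll0537), both at 0.02, nrtA (sll1450) at -0.01, nirA (slr0898) at -0.19 and urtD (sll0764) at 0.05 were among those that did not pass. The light-independent protochlorophyllide reductase has a further subunit beside those of chlN and chlL, and its gene chlB (slr0772) gave 0.39 ± 0.02 in the scanner files and 1.11 in the table.

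The authors' table and the scanner files order genes differently. Another processing, column order or sign of the same scans is argued against by the largest absolute correlation across genes, 0.26, over 12 settings and 15 channel pairs. Gene names shuffled among the lines of the table are argued against by genes with consecutive locus numbers, which correlated at 0.31 in the table and 0.37 in the scanner files, with 0.07 the highest of 1000 shuffles. A hypothesis that stays open is that the table may come from other hybridisations of the same strains, since scpB to scpE lay at a median percentile of 98.6 by absolute table value, whatever its sign. No biological explanation was tested.

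Phosphate genes were higher on arrays 1 and 2 but not on array 3. Processing is argued against, since the difference in the list's median was at least 2.43 in all scanner settings run, and swapped dyes on array 3 are argued against by the median of scpB to scpE there, -2.44. A candidate explanation is that the Scp-less RNA of arrays 1 and 2 differed from that of array 3. For each of the 13 genes, the level on array 3 was taken from the mean level on arrays 1 and 2. The median of these differences was 3.14 in Cy3 (0.05 to 6.26) and 0.38 in Cy5 (-0.27 to 1.14). Some genes were thus higher on arrays 1 and 2 in Cy5 as well, such as phoA at -1.15 and -1.33 against -2.38. Of 18 genes whose ratio on array 3 lay more than 1.5 from the mean of the other arrays, 12 were in the phosphate list. The labels name no difference between the replicates, so no biological explanation was tested.

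With the signs of the arrays turned in all 4 distinct ways, 1 choice, the real one, called 1482 genes and the highest of the others called 0. The choices are too few for a share under 0.05. The arrays correlated across genes at 0.71 to 0.89, so low counts for the other choices follow from that agreement. A dye effect particular to a gene would also repeat on all arrays, so no conclusion is drawn from these counts.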
